A study of Homo sapiens with 6 samples.

How the data were processed

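Total RNA from A549 cells, a human lung adenocarcinoma line, had been extracted with TRIzol and made into libraries with a VAHTS Universal V6 RNA-seq kit, per the labels' protocols. The labels placed 3 libraries in a dormant group and 3 in a group activated by medium conditioned by osteoclasts. Whether the libraries of a group came from separate cultures is not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical.

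The count table deposited by the authors held whole-number counts per gene symbol. The FPKM table deposited by the authors held the same counts divided by a gene length and by the total of the count table, since the ratio of count to FPKM between libraries equalled the ratio of the totals for every gene with at least 100 counts in both libraries compared. Per the submitters' processing notes, fastp, HISAT2, HTSeq and the build GRCh38 were used. Versions, the gene annotation and whether counting used strand are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart, and reads of near-identical copies may be split or lost. The table had 19470 symbols, of which 19078 were found in the RefSeq gene table of GRCh38.p14, and 99.7% of those were protein coding there. Mitochondrially encoded genes were not analysed here. Coordinates are 1-based, from that RefSeq table.

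The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, edgeR's default filter on low counts by group and Benjamini-Hochberg adjustment, with an adjusted p threshold of 0.05. Expression levels are TMM-normalised CPM, given as mean ± SD of 3 libraries. Standard errors of log2 fold changes were the log2 fold change divided by the square root of the F statistic. The procedure was tested on simulated counts for the 13336 genes tested in the activated against dormant comparison. The simulation changed 50 genes at each fold and left 13136 unchanged. It recovered 44% of genes changed 1.25-fold, 72% of those changed 1.5-fold, 90% of those changed 2-fold and 96% of those changed 4-fold, and 10 of its 161 calls were false. In the data 9830 genes passed, so the adjusted threshold fell at another unadjusted p, and these rates may not carry over.

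Gene lists were fixed before the data were examined, 31 in all, of which 30 had members in the tested genes. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry's directional p asks whether the genes of a list move one way on balance, and does not compare the list with other genes. Genes named in the text were also chosen by a rule fixed in advance. The rule took the 8 largest rises and the 8 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between groups. It also took, for each list with at least 3 members past the threshold, the 2 with the largest change in the majority direction and the 1 with the largest change in the other, or, for a list with fewer, those past it. MKI67, CCND1, CDKN1A, CDKN1B, MYC and NR2F1 were always included. Genes named outside this rule are marked as such.

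Alternatives set in advance were DESeq2 size factors, total counts or upper-quartile factors in place of TMM, DESeq2 1.42.0, limma voom, no filter or a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, leaving out each library, a fold minimum of 2, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 0.5 or no filter. A correction for gene length, a loess of each library's log2 CPM deviation on log2 gene length with a span of 0.3, was added after the data were seen. Intervals are exact binomial 95% intervals of a ratio of counts. They and the limit of 3 counts behind a count of 0 cover counting error only.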

Results

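RNA sequencing was used to compare A549 lung adenocarcinoma cells in an induced dormant state with A549 cells activated by medium conditioned by osteoclasts, the bone-resorbing cells, with 3 libraries per group. The comparison asked which genes differed as the cells passed from dormancy to activation. How dormancy was induced, and whether the groups shared a base medium, is not given in the sources used here. The sample titles tag the dormant libraries SF and the activated libraries OC, without expanding either tag. A difference between groups may therefore include a difference of medium. Total counts lay between 34128471 and 36667725 per library. Pearson correlations of log2 CPM across genes were 0.996 to 0.997 among dormant libraries, 0.995 to 0.996 among activated libraries and 0.928 to 0.931 between groups. Replicate counts differed by more than sampling noise, with a chi-square per degree of freedom of up to 10.9 among dormant libraries and 7.76 to 24.4 among activated libraries, so each library was counted once.

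Activated cells had higher levels of DNA replication, mitosis, glycolysis and hypoxia transcripts and lower levels of the amino acid response transcripts driven by the transcription factor ATF4. MKI67, a marker of cycling cells, rose from 72.1 ± 2.25 CPM (SD, n = 3) to 317 ± 39.5 CPM, a 4.39-fold change. CDC6, which loads the replicative helicase, rose 19.9-fold, and NUPR1, a stress-induced regulator, fell 91.6-fold. In all, 9830 of 13336 tested genes (73.7%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4868 of them higher and 4962 lower in activated cells. At least a 2-fold change was seen for 1493 higher and 1466 lower genes. The groups did not overlap for 76.5% of tested genes, against 10% by chance. With total counts in place of TMM factors, the split was 3941 higher and 5998 lower, and with unfiltered log2(FPKM + 1) in limma it was 3904 higher and 5998 lower. Total-count scaling moved the median log2 fold change of all genes by -0.14.

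The largest rises chosen by the rule included LBP, the lipopolysaccharide binding protein (chromosome 20, 38346482 to 38377013), which went from 0.0887 ± 0.0797 to 15.1 ± 2.08 CPM (log2 fold change 7.35 ± 0.32 SE, adjusted p = 3.64e-11). Its dormant level rested on 10 counts, and the ratio of counts was 169 (95% interval 91.8 to 354). Without dormant replicate 2 its fitted fold went from 163 to 259. SERPINB3 (chromosome 18, 63655197 to 63661893) rose from 1.86 ± 0.444 to 191 ± 30.7 CPM, and its neighbour SERPINB4 rose 89.7-fold. These serpins are near-identical copies, so their separate values are uncertain. CA9, a carbonic anhydrase induced by hypoxia, rose 93.7-fold. FAM111B rose 99.2-fold. FAM83A rose 62.2-fold, from dormant counts of 8, 7 and 0, and the amino acid transporter SLC6A14 59.1-fold, from 13, 6 and 4. Without dormant replicate 1 the fold of SLC6A14 was 90.03. ACTBL2, a beta-actin-like gene that shares sequence with abundant actins, had 6 dormant counts, all in replicate 1, and 935 activated counts, and is uncertain for both reasons.

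Among the largest falls, TXNIP, the thioredoxin-interacting protein (chromosome 1, 145992435 to 145996579), fell from 104 ± 15.3 to 0.447 ± 0.285 CPM (log2 fold change -7.84 ± 0.19 SE, adjusted p = 9.76e-14), a 229-fold change that was 346-fold without activated replicate 2. ATP6V0D2, a proton pump subunit known from osteoclasts, fell from 19.3 ± 1.72 to 0.0707 ± 0.0982 CPM, with 2164 dormant and 7 activated counts, 6 of them in replicate 3. Its fitted fold was 267, and 1073 without that library. HRK, which promotes apoptosis, fell 96.2-fold. ATF3, a stress-induced transcription factor, fell 83.2-fold and ULBP1, a ligand of the immune receptor NKG2D, fell 81.8-fold. KCP had 1294 dormant and 5 activated counts, the latter all in replicate 3. ADM2 had 1078 and 8, a 117-fold change that was 296-fold without activated replicate 3.

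**Figure D1:**
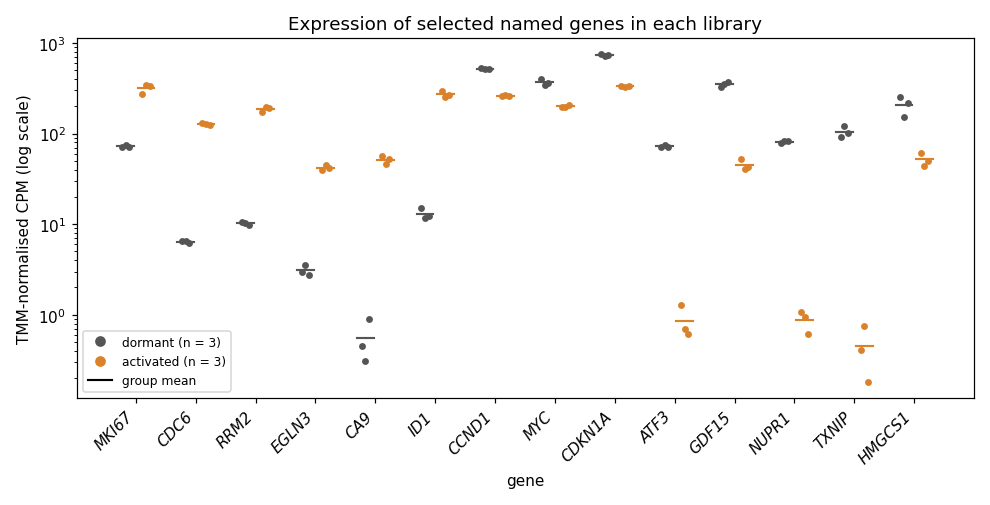
TMM-normalised CPM on a log axis for 14 named genes, with 1 point per library and a line at the mean of each group of 3. CDC6 rose 19.9-fold and NUPR1 fell 91.6-fold, while MKI67 and MYC moved in opposite directions.

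All 36 tested members of the DNA replication and G1/S list rose, with a median log2 fold change of 2.32 (camera adjusted p = 4.41e-55). Beside CDC6, RRM2, a subunit of ribonucleotide reductase, rose from 10.3 ± 0.382 to 187 ± 12.7 CPM. In the mitosis list, 29 of 30 members rose and 1 did not pass (median 1.63, camera adjusted p = 1.65e-19). CDC20, an activator of the anaphase-promoting complex, rose 7.42-fold and the kinase AURKB 5.12-fold. Both calls held with an estimated correlation, at adjusted p = 0.00674 and 0.0326. Of 20 cell cycle inhibitors and quiescence genes, 13 fell and 3 rose (camera adjusted p = 0.00238), and adjusted p = 0.102 with an estimated correlation. CDKN1C fell 11.9-fold, with activated counts of 10, 1 and 6, and 18.9-fold without activated replicate 1. FOXO3 fell 4.07-fold, while CDKN2C rose 4.21-fold. CDKN1A, the p21 inhibitor, fell 2.21-fold and CDKN1B, the p27 inhibitor, 1.56-fold. Growth-promoting genes did not all follow MKI67, since CCND1 fell from 520 ± 8.51 to 262 ± 4.96 CPM and MYC from 369 ± 27.0 to 199 ± 5.05 CPM.

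In the glycolysis and hypoxia list, 24 of 29 members rose and 3 fell (median 1.04, camera adjusted p = 9.01e-17), and the call held with an estimated correlation at adjusted p = 0.0186. EGLN3, an oxygen-sensing hydroxylase, rose 13.5-fold, while ADM fell 1.90-fold. Of 27 tested genes of the amino acid response, 25 fell and 1 rose (median -1.36, camera adjusted p = 2.47e-37), and adjusted p = 0.00735 with an estimated correlation. NUPR1 and ATF3 fell most among them, and VLDLR rose 1.24-fold, a call that missed the threshold with unfiltered log2(FPKM + 1). Of 21 ER chaperone and unfolded protein response genes, 14 rose and 7 fell (camera adjusted p = 0.0221), and adjusted p = 0.147 with an estimated correlation. PDIA4 and CRELD2, which act in protein folding in the endoplasmic reticulum, rose 3.67-fold and 4.28-fold, and ERN1, a sensor of unfolded proteins, fell 6.72-fold.

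**Figure D2:**
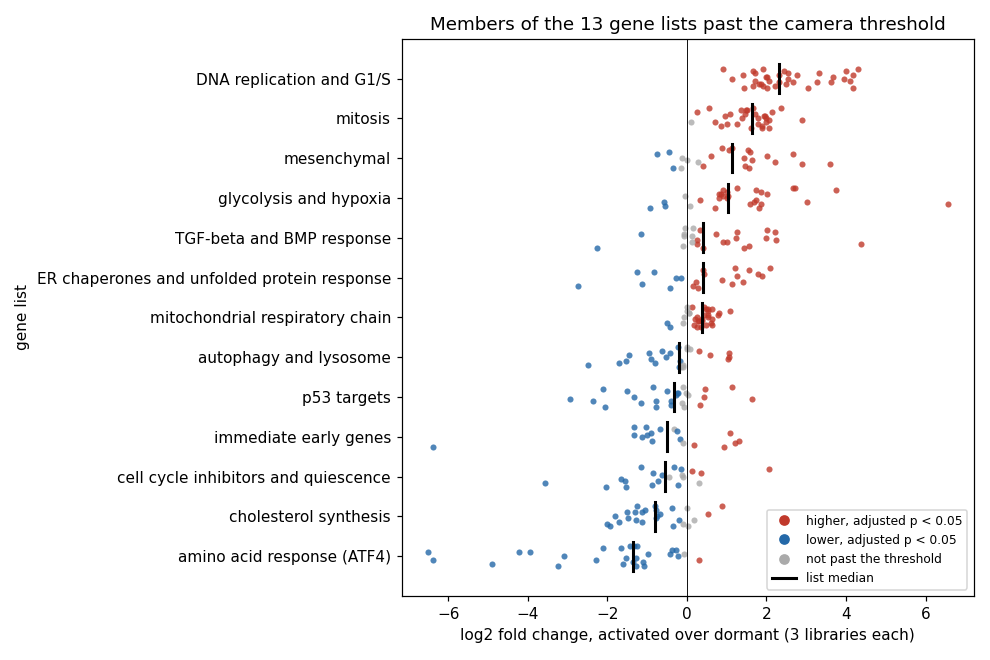
Log2 fold change, activated over dormant, of each tested member of the 13 gene lists past the camera threshold, with 1 point per gene, coloured by direction where the adjusted p was under 0.05, and a bar at each list's median. The DNA replication list had the highest median, 2.32, and the amino acid response list the lowest, -1.36.

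Cholesterol synthesis genes fell in 20 of 26 cases and rose in 2 (median -0.80, camera adjusted p = 0.00285), and adjusted p = 0.785 with an estimated correlation. With the replicate number as a block, the list's camera adjusted p was 4.43e-08. HMGCS1, an early enzyme of the pathway, fell from 207 ± 52.9 to 51.7 ± 8.49 CPM, and INSIG1 fell 3.82-fold. Of 33 respiratory chain genes encoded in the nucleus, 25 rose and 2 fell (21 and 5 with total counts, median 0.38, camera adjusted p = 0.0316), and adjusted p = 0.785 with an estimated correlation. This call also ended with total counts (adjusted p = 0.0642), without activated replicate 1 (0.0535) and after a correction for gene length (0.369). NDUFS3 rose 2.13-fold and SDHD fell 1.42-fold. In the autophagy and lysosome list, 13 of 24 members fell and 5 rose (camera adjusted p = 0.0221), and adjusted p = 0.693 with an estimated correlation. SQSTM1, an autophagy receptor that overlaps other genes, fell 5.65-fold, while the protease CTSB rose 2.10-fold. Of 26 p53 targets, 16 fell and 5 rose (camera adjusted p = 0.00129), and adjusted p = 0.0936 with an estimated correlation. GDF15 fell 7.73-fold and BBC3, which promotes apoptosis, 5.16-fold, while TP53I3, which overlaps another gene, rose 3.09-fold. Immediate early genes fell in 11 of 18 cases and rose in 5 (camera adjusted p = 0.0316), and adjusted p = 0.424 with an estimated correlation. ATF3, also a member of the amino acid response list, fell most (log2 fold change -6.38), and CCN2 rose 2.49-fold. The next largest fall, of NR4A2, was -1.34 on the log2 scale, and the list was not tested without ATF3.

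Of 25 tested TGF-beta and BMP response genes, 16 rose and 2 fell (13 and 5 with total counts, median 0.41, camera adjusted p = 3.89e-05), and adjusted p = 0.129 with an estimated correlation. ID1, a target of BMP signalling, rose 20.8-fold to 270.4 ± 20.8 CPM, and TGFBI rose 4.69-fold. The BMP antagonist NOG fell 4.82-fold, from dormant counts of 30, 28 and 44 to activated counts of 5, 5 and 9. NOG passed the filter on low counts only through the dormant group and could only be seen to fall. In the mesenchymal list, 16 of 23 members rose and 3 fell (median 1.14, camera adjusted p = 0.000135), and adjusted p = 0.119 with an estimated correlation. THY1 rose 12.2-fold and the collagen gene COL5A1 7.44-fold, and the receptor AXL fell 1.70-fold.

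The other lists did not pass camera's threshold. Of 21 epithelial genes, 13 fell and 6 rose, and of 16 dormancy-associated genes, 8 rose and 6 fell (6 and 6 with total counts). NR2F1, a regulator linked to dormancy, rose 1.78-fold, TGFB2 rose 2.97-fold and BHLHE41, which overlaps another gene, fell 9.37-fold. Of 17 bone metastasis and osteolysis genes, 8 rose and 5 fell. ITGB3, the integrin beta 3 subunit, rose from 5.88 ± 0.609 to 265 ± 41.4 CPM and IL11 rose 5.54-fold. In the NF-kB and inflammatory list, 11 of 25 members rose and 9 fell, which turned to 8 and 11 with total counts and to 9 and 10 after the length correction. The chemokine genes CCL2 and CXCL5 rose 6.12-fold and 5.79-fold, and PTGS2 fell 4.68-fold. Of 23 interferon response genes, 10 rose and 11 fell. Of 30 NRF2 targets, 17 fell and 10 rose, and this list passed with total counts (adjusted p = 0.0371), without activated replicate 1 (0.0193) and after the length correction (0.00866). Fatty acid synthesis genes fell in 8 of 14 cases and rose in 3 (8 and 1 with total counts), with LPIN1 4.89-fold lower, and this list passed without dormant replicate 2 (adjusted p = 0.0405). ERK pathway output genes fell in 11 of 20 cases and rose in 5. Of 20 YAP/TEAD targets, 9 rose and 8 fell (9 and 10 with total counts), and of 19 WNT and NOTCH response genes, 5 rose and 8 fell (8 and 8 after the length correction). Lung and foregut lineage genes rose in 4 and fell in 4 of 12 cases. Ribosome biogenesis genes rose in 13 and fell in 10 of 29 cases, which turned to 7 and 14 with total counts. Ribosomal protein genes rose in 13 and fell in 4 of 42 cases, which turned to 3 and 18 with total counts and to 5 and 26 after the length correction. Their median of 0.05 became -0.09 and -0.16. Of 8 replication-dependent histone genes, 3 rose and 2 fell, which turned to 2 and 3 after the length correction. Ribosomal protein and histone genes have near-identical copies and are uncertain. The median, mean and test differed in sign for the YAP/TEAD, WNT and NOTCH, osteoclast marker and lung lineage lists, the last only for fry. Counts adjusted over the list alone were the same for every tested list except ribosomal proteins (10 higher, 2 lower) and osteoclast markers (4 higher, 5 lower).

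Among markers of other cell types, 10 of 14 listed osteoclast markers and 6 of 18 listed myeloid markers had enough counts to be tested. Of the osteoclast markers, 4 rose and 4 fell, and all 6 tested myeloid markers rose (4 with total counts), without passing camera (adjusted p = 0.466 and 0.203). The myeloid markers LAPTM5, with 7 to 9 counts per dormant library, and CSF1R, with 0 to 6, passed the filter only through the activated group. So did the osteoclast marker MMP9, with 5 or 6 counts per dormant library. These markers could therefore only be seen to rise. Some markers outside the rule for named genes, both well expressed and undetected, are named here after their values were seen. TCIRG1 rose from 67.8 ± 1.48 to 197 ± 2.50 CPM and CD14 from 1.10 ± 0.396 to 9.25 ± 0.478 CPM, and each overlaps another gene. CD68 went from 135 ± 5.75 to 152 ± 3.82 CPM, a rise that ended with total counts (log2 fold change 0.03, adjusted p = 0.579), as did that of ITGAX (adjusted p = 0.0508). NFATC1 fell from 16.4 ± 0.238 to 9.04 ± 0.753 CPM and CTSK from 8.31 ± 1.03 to 6.29 ± 0.495 CPM, while ITGB3, given above, rose 45.1-fold. LAPTM5 rose from 0.224 ± 0.0385 to 2.10 ± 0.228 CPM and CSF1R from 0.0877 ± 0.0812 to 0.774 ± 0.117 CPM, 8.42-fold, or 13.8-fold without dormant replicate 1. Of 6 osteoblast and stromal markers, 5 rose and 1 fell (adjusted p = 0.605). DCN and PDGFRA passed the filter only through the activated group and could only be seen to rise. PDGFRA had dormant counts of 1, 6 and 6. DCN had 1 dormant and 46 activated counts, a ratio of 50.7 (95% interval 8.65 to 2044). Its fitted fold was 36.6, and 127 without dormant replicate 2. TYROBP, an abundant transcript of osteoclasts and myeloid cells, had 0 counts in all libraries, which allows up to 0.0281 CPM over the activated group. DCSTAMP, OCSTAMP, CALCR, AIF1, C1QA, C1QB and C1QC also had 0 counts in all libraries, and ACP5 had 63 dormant and 5 activated counts.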

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

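The gene length correction was chosen after the data were seen, and the other settings before. The number of changed genes, 9830, was between 9109 and 10009 under the alternative scalings, tools, filters and units. With a fold minimum of 2 it was 2959, with 1493 higher and 1466 lower, by construction. Leaving out 1 library gave between 9298 and 9756 changed genes, 4625 to 4836 higher and 4645 to 4920 lower. Of the 9830 calls, 99.3% were kept in the same direction with DESeq2 size factors, 90.6% with total counts, 92.3% after the length correction, which called 18 of them in the opposite direction, and 89.2% with unfiltered log2(FPKM + 1). The share was 82.9% with filtered log2(FPKM + 1) and 82.7% with log2(FPKM + 0.1), whose filter left 9035 of the calls to be tested. The higher share of the calls, 49.5%, was 39.7% with total counts and 40.3% with filtered log2(FPKM + 1), which is scaled by the same totals. Of 1798 values of the 101 named genes, 1797 kept their direction and side of the threshold, VLDLR being the exception. Most of these genes were picked for large changes past the threshold, so this stability was largely built in.

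Of 13 lists past the threshold, 4 passed with an estimated correlation, and fry called 24, since it does not compare a list with other genes. Correlation above the preset does not account for every call lost with the estimate. The estimate was -0.00074, -0.0082 and -0.042 for the ER chaperone, p53 target and cell cycle inhibitor lists, below the preset of 0.01. The loss of their calls is therefore no evidence that the members of these lists vary together. Leaving out 1 library gave 13 to 14 lists. No list called in the main test turned direction in 390 values, of which 12 lost and 16 gained a call. With the replicate number as a block, 9789 genes changed, 4847 higher and 4942 lower, and 14 lists passed, fatty acid synthesis being added (adjusted p = 0.0382). Deviations of libraries that share a number correlated at only 0.0275, 0.0336 and 0.0286, so the numbers were not taken as pairs, although each library correlated best with its own number. Some genes did follow the number, since HMGCS1, INSIG1 and SCD were highest in replicate 1 and lowest in replicate 2 of both groups. An effect shared by libraries of 1 number was therefore not excluded. Depth limited genes with few counts, such as DCN and CSF1R.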

Other observations

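The test of falling osteoclast markers and the gene length correction were chosen after the data were seen, and the genes of the first 2 paragraphs that opened each pattern were chosen after their values were seen. The members used to test both patterns were listed before their values were seen. Several transcripts of the circadian clock, the cell's daily oscillator, were lower in activated cells. NR1D1 fell from 103 ± 3.08 to 14.7 ± 0.354 CPM, NR1D2 from 127 ± 6.63 to 16.5 ± 0.862 CPM and PER3 fell by 2.94 on the log2 scale. A hypothesis of a shifted clock predicted falls of other output and repressor genes and rises of at least 2 of ARNTL, CLOCK, NPAS2 and NFIL3. All 6 output and repressor genes listed (PER1, PER2, DBP, TEF, HLF and CRY2) were lower, but 0 of the 4 others rose, 3 fell and ARNTL did not pass (log2 fold change 0.16, adjusted p = 0.148). Camera on these 10 genes, added later, asked for a common change and not for the predicted mix of falls and rises. Its direction was down, with p = 0.0130, and p = 0.224 with an estimated correlation. The prediction was therefore met in part only, and a shift of phase cannot be told apart from a general fall of clock transcripts with 1 time point per group.

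Transcripts of acute phase proteins, which the liver secretes in inflammation, moved in both directions. FGA rose from 9.09 ± 1.96 to 103 ± 5.69 CPM, FGB from 1.80 ± 0.307 to 55.2 ± 3.70 CPM and FGG had a log2 fold change of 4.15 ± 0.15 SE. Of 12 other acute phase genes tested, 7 rose (58.3%), 3 fell and 2 did not pass, with CFB among the higher and SERPINA3, HPX and ITIH4 lower. Camera on these 12 gave p = 0.0631, and p = 0.298 with an estimated correlation. The hypothesis of a broad acute phase response was neither met nor excluded by the bounds set for it. CRP had 0 dormant and 41 activated counts, at least 15.1-fold higher against 3 counts over the group. Of the 12 genes, CRP passed the filter on low counts only through the activated group and could only be seen to rise. HPX, at 1.03 ± 0.778 CPM in dormant and 0.0295 CPM in activated cells, passed only through the dormant group. It could only be seen to fall. ARRDC4, a relative of TXNIP picked after its value was seen, fell from 32.0 ± 3.02 to 1.19 ± 0.372 CPM.

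The breadth of the change, 9830 genes, was set against technical explanations. Only 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, and the highest other split gave 0 genes in edgeR's test (at most 48 at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05. Every other split mixes the groups, so their difference enters its spread and few calls were bound to result, and the contrast is no evidence by itself. Log2 fold change fell weakly with gene length (Spearman rho -0.14 across 13336 genes). Its median was 0.14 for the 3335 shortest genes and -0.17 for the 3334 longest. A correction for gene length kept 92.3% of the calls in the same direction. It removes only a smooth trend, and with so small a trend a high share was largely built in. The size of the trend, set against 2959 genes changed at least 2-fold, argues against a smooth length bias as the whole cause. Other forms of length bias were not tested. Total-count scaling moved the higher share of the calls by 9.87 percentage points, under the bound of 10 set in advance, but leaving out 1 library gave 9.77 to 10.7. How the calls split between higher and lower therefore cannot be told apart from the choice of scaling.

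RNA of osteoclasts or other myeloid cells carried over with the medium was weighed by bounds set before the data were examined, and these decided nothing. The median log2 fold change of the 16 tested osteoclast and myeloid markers was 0.64, below the bound of 1, but it pooled a median of -0.28 for osteoclast and 1.93 for myeloid markers, and CTSK and LAPTM5 exceeded 1 CPM in every activated library, against the other bound. CTSK had 282 to 369 counts per dormant library and 202 to 234 per activated library, so that bound was poorly chosen. LAPTM5 and CSF1R, which count toward the myeloid median, passed the filter on low counts only through the activated group. In the later test, 4 of the 10 tested osteoclast markers, ACP5, CTSK, NFATC1 and ATP6V0D2, were lower past the threshold, and 4 to 5 were under each scaling. Another 4 rose in the main test, among them MMP9, which passed the filter on low counts only through the activated group. The bound of the later test was set after the counts were seen, so meeting it is no support. ACP5 and ATP6V0D2 passed the filter on low counts only through the dormant group, as did OSCAR, which was also lower with total counts. TYROBP, DCSTAMP, OCSTAMP and CALCR had 0 counts in all libraries. These values, rather than the bound, argue against human osteoclast RNA as the whole source of the changes. A smaller carried-over share cannot be told apart from expression by the A549 cells, and RNA of another species was not tested. Activation by the medium stays an untested biological hypothesis.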
